A study of Mus musculus with 10 samples.

How the data were processed

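The deposited data of each library are a table of HTSeq counts per Ensembl gene, which the authors made from total RNA of mammary gland cells sorted by flow cytometry after antibody staining. According to the labels, RNA was extracted with the RNeasy Micro kit of Qiagen, libraries were built with the Ovation Solo RNA-Seq system of NuGen and sequenced on an Illumina NovaSeq instrument. The submitters' processing notes name STAR, HTSeq and the mouse genome GRCm38 (mm10). Versions of these tools, the annotation release and the strand setting are not given in the sources used here, so overlapping antisense genes could not be told apart.

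Libraries were assigned to the 5 populations by the cell type in their labels. Replicates 1 and 2 follow the order of the sample records. No pairing of libraries is stated, and replicate numbers were not treated as pairs. All values below come from the deposited counts. The 5 summary entries of HTSeq were removed first, and the share of reads it left unassigned was kept for quality control. Reads without a feature made up 12.6% to 30.8% of the total, ambiguous reads 2.71% to 3.48% and reads without a unique alignment 14.6% to 43.0%, the last highest in THC replicate 1. The count of reads with low alignment quality equalled that of reads without a unique alignment in every library and was counted once.

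Gene identifiers were matched to symbols and GRCm38 positions in GENCODE M21, where 49412 of 49671 were found and 259 were not. After the filter of edgeR on group size (filterByExpr), 19757 genes were tested, of which 19691 had a matched symbol. Normalization factors were those of TMM. Counts scaled to library size (CPM) use these factors, and log2 CPM a prior count of 2. The test was edgeR's quasi-likelihood F-test with robust fitting on all 10 libraries with 1 coefficient per population, which leaves 5 residual degrees of freedom, at a common dispersion of 0.0715. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Between libraries of the same population, counts varied far more than by counting error alone, with a chi-square per degree of freedom of 18.1 to 32.4. R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0 were used.

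The comparisons, the test, most alternatives, the naming rule and 26 gene lists of lineages, pathways, stress and other cell types were fixed before the data were examined. The lists were written from textbook knowledge, and 25 had at least 2 measured members and were tested. Amph, Lef1, Ccl20, Hes5, Sox2, Higd1b, 4 milk protein genes, 5 squamous genes, 7 adipocyte genes, 7 erythrocyte genes and 9 skeletal muscle genes were among those without enough counts. A few genes stand in both of a pair of lists, such as Jag2, Areg, Csn3, Lgr5 and Notch3. Lists were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists within a comparison. Member counts adjusted over the list alone apply Benjamini-Hochberg to that list's members only.

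Genes to be named were set by rule: the 6 highest and 6 lowest log2 fold changes among called genes with at least 10 CPM in the higher population and no overlap between libraries, up to 3 called members per list with the smallest adjusted p, and 12 anchor genes in every main comparison. From the genes this rule gave, those whose calls held under more alternatives were preferred in the text, a choice made after the results were seen. Members of fixed lists such as Pecam1, Col1a1, Mki67, Top2a, Myh11 and Cnn1 were named where their list is described. Sfrp4, Tmem56, Piezo2, Galnt15, H2-Q6, Ace, Lipa, Gimap8 and Cald1 fell outside the rule and were named after their values were seen. Fold changes of genes with 3 counts or fewer in the lower population are given as a bound from 3 counts, or as a pooled ratio with a 95% counting interval.

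The alternatives fixed at the start were RLE and upper-quartile factors, DESeq2, limma-voom, no filter and a stricter filter of 5 CPM in 2 libraries, the set of library numbers as a term, a 2-fold threshold, a fit of only the 2 populations compared, and leaving out each library in turn. Leaving out a library leaves a population with 1 library, whose spread is then taken from the other populations. The low-count filter was applied anew in these fits, so each tested more genes than the fit of all libraries. They also have fewer degrees of freedom. After the data were seen, a fit with the endothelial list mean as a covariate and a fit of counts thinned to 2757773 per library, with 15492 genes tested, were added. The endothelial list mean was highest in both THC libraries, so that covariate also takes up differences of THC from the other populations. Gene calls count as held when the call and its direction stayed, so a gene that was not called and changed sign counts as unchanged. The pipeline was tested on simulated data with 200 changed genes. For TBC vs BC, 3 of 50 genes changed 2-fold and 29 of 50 changed 4-fold were recovered, with 11 false calls among 83. At most 8% of 2-fold changes were recovered in any simulated comparison. With only 200 genes changed, the adjusted p cutoff was stricter there than in real comparisons with many called genes. The recovered shares therefore do not carry over to those comparisons. Genes that did not pass may still differ. Reads, cell sorting records and images were not analysed here.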

Results

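Mouse mammary gland cells of 5 sorted populations were profiled by RNA sequencing, with 2 libraries per population and 10 libraries in all. Basal cells (BC) and luminal cells (LC) carried no treatment label, and the second library of each was labelled wild type. Tomato basal cells (TBC), Tomato hybrid cells (THC) and Tomato luminal cells (TLC) were labelled as treated by luminal cell ablation. Tomato is a red fluorescent reporter that marks chosen cells and their descendants. The populations address how far marked cells carry basal and luminal genes after luminal cells have been removed. Every comparison of a Tomato population with BC or LC contrasts ablation and Tomato marking at once. The labels give no mouse line for any library, so whether both libraries of BC and of LC came from mice of the same genotype is unknown. Counts assigned to genes were 5381351 and 12286209 in BC, 9746963 and 13685674 in LC, 6730120 and 13270498 in TBC, 2757773 and 13601753 in THC, and 5632671 and 9799263 in TLC, for replicates 1 and 2. THC replicate 1 was the shallowest library, where 3 counts equalled 1.16 normalized counts (CPM, scaled to library size), against 0.202 in THC replicate 2. Of 49671 gene identifiers, 19757 had enough counts to be tested. Nothing in the labels says that the libraries of a population came from separate animals, so every p measures only the spread between these samples. Counting intervals and floors for genes with few counts cover counting error only.

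THC lay between basal and luminal populations in both gene lists that define the lineages. The basal and myoepithelial list of 20 genes averaged 9.27 ± 0.29 (SD, n = 2) log2 CPM in BC, 9.53 ± 0.20 (SD, n = 2) in TBC, 8.11 ± 0.07 (SD, n = 2) in THC, 5.87 ± 0.21 (SD, n = 2) in TLC and 3.83 ± 0.47 (SD, n = 2) in LC. The pan-luminal list of 20 genes ran the other way, at 5.56 ± 0.08 (SD, n = 2) in BC, 5.16 ± 0.20 (SD, n = 2) in TBC, 6.95 ± 0.04 (SD, n = 2) in THC, 7.52 ± 0.02 (SD, n = 2) in TLC and 8.22 ± 0.10 (SD, n = 2) in LC. On the basal list the lower TLC library stood 1.56 log2 units above the higher LC library. The first principal component of log2 CPM held 47.4% of the variance and placed BC and TBC at -83.9 to -67.4, THC at -6.18 and -0.601, TLC at 46.1 and 55.5 and LC at 103 and 119. The second, with 19.2%, placed BC and LC at -54.8 to -39.8 and TBC at -0.211 and 7.35. On it THC lay at 86.3 and 27.4 and TLC at 63.5 and 13.5 in replicates 1 and 2, so it also set these replicates apart.

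**Figure D1:**
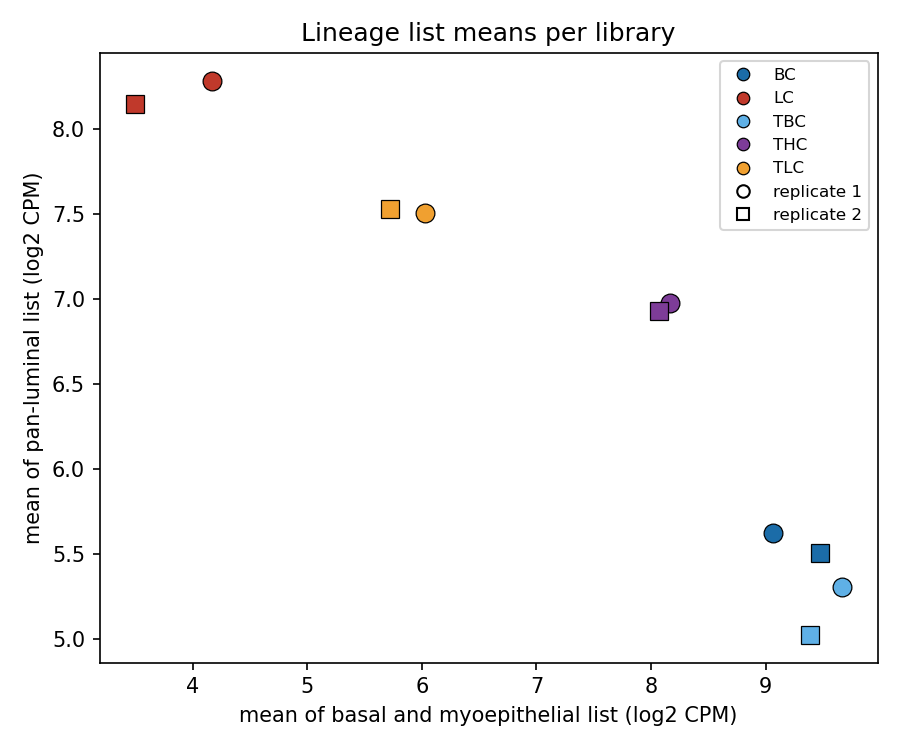
Mean log2 CPM of the 20 genes of the basal and myoepithelial list against the 20 of the pan-luminal list, with 1 point per library. Both THC libraries lie between the TBC libraries and the TLC libraries on both axes.

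LC and BC were compared to learn which genes separate the lineages without ablation. LC held little of the basal keratins and contractile proteins. Krt14 (ENSMUSG00000045545, 11:100203162-100207548), a keratin of basal epithelium, stood at 22.7 ± 17.1 CPM in LC against 2280.3 ± 90.6 in BC (SD, n = 2 each). Acta2, the smooth muscle actin that lets myoepithelial cells contract, stood at 23.7 ± 15.9 CPM in LC against 2097 ± 830.1 in BC (SD, n = 2 each). Simple-epithelium keratins were higher in LC, with Krt8 (ENSMUSG00000049382, 15:101996698-102004482) at 2078 ± 436 CPM in LC against 367 ± 70.6 in BC (SD, n = 2 each). So were the receptors of hormone-sensing cells, with Esr1 at 456 ± 78.8 CPM in LC against 49.3 ± 10.96 in BC (SD, n = 2 each). Frmpd4 (ENSMUSG00000049176, X:167471309-168577231), which encodes a scaffold protein of synapses, had 0 counts in LC and 17.6 ± 10.7 (SD, n = 2) CPM in BC, at least 159-fold higher. In log2 fold changes, the basal genes Krt14 (-6.66), Krt5 (-6.99), Trp63 (-6.02), Acta2 (-6.48), Tpm2 (-6.005) and Jag2 (-5.76) were lower, where Trp63 maintains basal epithelium and Jag2 is a Notch ligand. The luminal genes Krt8 (2.50), Krt18 (2.79), Krt19 (3.72), Krt7 (3.75), Epcam (2.13), Cldn7 (3.45) and Cldn3 (3.43) were higher, the last being tight-junction claudins. Of the basal and myoepithelial list 20 of 20 were lower and none were higher (0 and 20 adjusted over the list alone). The list median was -5.96 log2 units (camera adjusted p = 2.9e-51, adjusted p = 0.012 with an estimated correlation). Of the pan-luminal list 19 of 20 were higher, none were lower and 1 did not pass (20 and 0 adjusted over the list alone). Its members had a median log2 fold change of 2.76 (camera adjusted p = 8.8e-26, adjusted p = 0.0070 with an estimated correlation). Hormone-sensing genes were higher too, among them Esr1 (3.20), Pgr (3.19), Areg (4.51), Foxa1 (4.26) and Wnt4 (3.96), where Areg and Wnt4 are signals that hormone-sensing cells send to their neighbours. Of that list 10 of 14 were higher, none were lower and 4 did not pass (13 and 0 adjusted over the list alone). Their median log2 fold change was 3.96 (camera adjusted p = 2.0e-20, adjusted p = 0.027 with an estimated correlation). With Tnfsf11, which had 0 counts in BC, at its bound the median was 3.86.

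Genes of the alveolar lineage were also higher in LC than in BC, with Elf5 (3.06), Aldh1a3 (2.98) and Wfdc18 (2.36) among progenitor genes and Btn1a1 (2.999), which coats milk fat droplets, among milk protein genes. Of the progenitor and alveolar list 11 of 16 were higher, none were lower and 5 did not pass (11 and 1 adjusted over the list alone). The median over these genes was 2.52 (camera adjusted p = 6.2e-07, adjusted p = 0.34 with an estimated correlation). Of the milk protein list 4 of 9 were higher, none were lower and 5 did not pass (6 and 0 adjusted over the list alone). Across that list the median was 2.52 (camera adjusted p = 0.0016, adjusted p = 0.47 with an estimated correlation). Wnt targets and feedback genes were mostly lower, with Lgr5 (-6.53) and Wif1 (-7.12), although Ccnd1 (3.16), a cyclin that starts the cell cycle, was higher. Of that list 1 of 14 were higher, 11 were lower and 2 did not pass (1 and 11 adjusted over the list alone). A median of -2.19 was found over the list (camera adjusted p = 2.6e-07, adjusted p = 0.21 with an estimated correlation). The Notch list ran both ways, with Notch3 (2.87) higher and Dll1 (-4.96) lower. Of its members 3 of 18 were higher, 6 were lower and 9 did not pass (5 and 7 adjusted over the list alone). Members had a median of -0.25 (camera adjusted p = 0.21, adjusted p = 0.80 with an estimated correlation). Of EGFR ligands and MAPK feedback genes 4 of 19 were higher, 6 were lower and 9 did not pass (4 and 7 adjusted over the list alone). Over all its genes the median was 0.00 (camera adjusted p = 0.77, adjusted p = 0.88 with an estimated correlation). Unfolded-protein response genes were higher as far as they passed (median 0.88, camera adjusted p = 0.0085, and adjusted p = 0.69 with an estimated correlation). Schwann and nerve genes were lower as a list (median -1.66, camera adjusted p = 0.015, and adjusted p = 0.21 with an estimated correlation). For p53 targets the median was -0.12 and the mean 0.08 (camera adjusted p = 0.985, adjusted p = 0.994 with an estimated correlation). Fibroblast genes were lower in LC too (median -2.18, camera adjusted p = 0.0016, and adjusted p = 0.38 with an estimated correlation). Pericyte genes (median -1.26, camera adjusted p = 0.32, and adjusted p = 0.80 with an estimated correlation), endothelial genes (median -0.99, camera adjusted p = 0.11, and adjusted p = 0.81 with an estimated correlation) and immune genes (median -0.72, camera adjusted p = 0.63, and adjusted p = 0.88 with an estimated correlation) had negative medians without passing as lists, and the endothelial mean was 4.78 log2 CPM in BC replicate 1 but 3.01 in BC replicate 2. Adipocyte genes (median -1.12, camera adjusted p = 0.95, and adjusted p = 0.973 with an estimated correlation) and the pair of skeletal muscle genes measured (median -0.44, camera adjusted p = 0.83, and adjusted p = 0.88 with an estimated correlation) did not pass as lists. Alas2, the only erythrocyte gene measured, stood at 5.79 ± 2.37 CPM in LC against 3.74 ± 1.08 in BC (SD, n = 2 each). Further higher genes were Ido1 (5.14), Itih2 (4.69) and Tnf (2.64), which encode an enzyme of tryptophan breakdown, a hyaluronan-binding protein and a cytokine. Of TNF and NF-kappaB targets 10 of 23 were higher, 4 were lower and 9 did not pass (12 and 4 adjusted over the list alone). The list median was 0.76 log2 units (camera adjusted p = 0.037, adjusted p = 0.72 with an estimated correlation). Further lower genes were Egr2 (-4.16) and Ccn2 (-4.59). In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 2274 genes higher and 2468 lower in LC. The camera test called 16 of 25 lists, of which the basal, pan-luminal and hormone-sensing lists held with an estimated correlation. The directional test of fry, which asks whether a list moved on balance one way, called 12, and its mixed test, which asks for changes in either direction, called 20, but neither compares a list with other genes. The total was 3131 without LC replicate 2.

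TBC and BC were compared to learn what changed in basal cells after luminal ablation. No single gene passed edgeR's test. In simulated data for this comparison the test recovered 3 of 50 genes changed 2-fold and 29 of 50 changed 4-fold, so smaller changes could be missed. Of the basal identity genes Krt14 stood at 1527 ± 278 CPM in TBC against 2280.3 ± 90.6 in BC (SD, n = 2 each) and Acta2 at 3192 ± 637 CPM in TBC against 2097 ± 830.1 in BC (SD, n = 2 each). The largest list difference lay in the cell cycle, where 27 of 28 members had positive log2 fold changes with a median of 2.25. Mki67, a marker of dividing cells, stood at 160.4 ± 128 CPM in TBC against 13.5 ± 3.09 in BC (SD, n = 2 each). Top2a, which untangles chromosomes at division, stood at 95.98 ± 95.3 CPM in TBC against 6.88 ± 1.69 in BC (SD, n = 2 each). Adjusted over the list alone, 22 cell cycle members rose and 0 fell (camera adjusted p = 5.0e-34, adjusted p = 0.26 with an estimated correlation). The cell cycle mean was 3.33 log2 CPM in TBC replicate 1 and 5.23 in TBC replicate 2, against 2.24 ± 0.11 (SD, n = 2) in BC. On the basal side Krt5 (0.00, adjusted p = 0.999), Krt14 (-0.58, adjusted p = 0.78), Trp63 (0.29, adjusted p = 0.82) and Acta2 (0.61, adjusted p = 0.72) did not pass, nor did Krt8 (-0.28, adjusted p = 0.84), Krt18 (-0.69, adjusted p = 0.62), Krt19 (-0.18, adjusted p = 0.88) and Epcam (-0.46, adjusted p = 0.66) on the luminal side. Among hormone receptors, the alveolar factor Elf5 and the cytokine Tnf the values were Esr1 (-0.33, adjusted p = 0.72), Pgr (0.16, adjusted p = 0.91), Elf5 (-0.31, adjusted p = 0.88) and Tnf (-0.87, adjusted p = 0.60). Interferon-stimulated genes, which answer viral and damage signals, had 20 of 24 positive values (median 0.54, camera adjusted p = 0.00060, and adjusted p = 0.69 with an estimated correlation). Their mean was 4.19 log2 CPM in TBC replicate 1 but 2.79 in TBC replicate 2, which lay within the 2.70 to 2.92 of the BC libraries. Medians were negative for pan-luminal genes (median -0.41, camera adjusted p = 0.0013, and adjusted p = 0.26 with an estimated correlation), progenitor and alveolar genes (median -0.60, camera adjusted p = 7.4e-05, and adjusted p = 0.69 with an estimated correlation) and immediate-early stress genes (median -0.52, camera adjusted p = 2.9e-10, and adjusted p = 0.26 with an estimated correlation). For the epithelial-mesenchymal transition regulators the median was -0.10 while the mean was 0.38 and camera called the list up (camera adjusted p = 0.023, adjusted p = 0.69 with an estimated correlation). With edgeR's quasi-likelihood test 0 genes were higher and 0 lower, at a smallest adjusted p of 0.181, although 1725 genes had raw p under 0.05, against 987.85 by chance. Of these, 902 were higher and 823 lower. DESeq2 called 207 genes, 165 higher and 42 lower, and limma-voom 0. Without the low-count filter edgeR called 398, Mki67 among them. Of 25 lists, camera called 13, none with an estimated correlation, and the directional test of fry called 0. The total was 3 without BC replicate 2, 148 without TBC replicate 1 and 2 without TBC replicate 2. Without TBC replicate 1, adjusted p lay between 0.00042 and 0.00044 for Mki67 and Top2a.

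THC and BC were compared to learn how hybrid cells depart from basal cells. Luminal genes rose in THC, with Cldn7 (ENSMUSG00000018569, 11:69964779-69967885) at 56.7 ± 3.64 CPM in THC against 12.1 ± 1.21 in BC (SD, n = 2 each). Foxa1, a transcription factor that opens chromatin for hormone receptors, rose to 210.0 ± 21.9 CPM in THC against 26.3 ± 9.21 in BC (SD, n = 2 each). The largest rise by the naming rule was of the casein Csn1s2a (ENSMUSG00000061937, 5:87774567-87788797), a milk protein, at 116 ± 41.9 CPM in THC against 0.434 ± 0.494 in BC (SD, n = 2 each). Cell division genes rose as well, with Cenpe, a motor protein of the mitotic spindle, at 87.1 ± 5.39 CPM in THC against 1.82 ± 0.912 in BC (SD, n = 2 each). Krt14 stood at 895 ± 378 CPM in THC against 2280.3 ± 90.6 in BC (SD, n = 2 each). The differences of Krt5 (-1.04, adjusted p = 0.19), Krt14 (-1.35, adjusted p = 0.14), Acta2 (-0.88, adjusted p = 0.25) and Tnf (1.35, adjusted p = 0.074) did not pass. Pan-luminal genes that rose included Cldn7 (2.23), Cldn3 (2.10) and Krt19 (2.33). Of that list 13 of 20 rose, none fell and 7 did not pass (16 and 0 adjusted over the list alone). Its members had a median log2 fold change of 1.52 (camera adjusted p = 6.2e-17, adjusted p = 0.019 with an estimated correlation). Hormone-sensing genes that rose included Areg (3.49), Foxa1 (2.98) and Cited1 (3.44). Of that list 10 of 14 rose, none fell and 4 did not pass (11 and 0 adjusted over the list alone). Their median log2 fold change was 2.48 (camera adjusted p = 1.3e-20, adjusted p = 0.035 with an estimated correlation). Among milk protein genes, with Csn1s2a (8.49) and Csn2 (7.07), 6 of 9 rose, none fell and 3 did not pass (8 and 0 adjusted over the list alone). The median over these genes was 2.70 (camera adjusted p = 4.3e-09, adjusted p = 0.22 with an estimated correlation). Among cell cycle genes, with Cenpe (5.46) and Aurkb (6.05), 22 of 28 rose, none fell and 6 did not pass (25 and 0 adjusted over the list alone). Across that list the median was 3.14 (camera adjusted p = 1.4e-28, adjusted p = 0.20 with an estimated correlation). Without BC replicate 1, adjusted p lay between 0.075 and 0.11 for Aurkb and Csn2. Without BC replicate 2, adjusted p lay between 0.11 and 0.17 for Aurkb, Csn1s2a and Csn2. Without THC replicate 1, adjusted p lay between 0.086 and 0.14 for Aurkb and Csn2. Without THC replicate 2, adjusted p lay between 0.076 and 0.13 for Aurkb and Csn2.

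Basal genes partly fell in THC against BC, with Dkk3 (-2.13), which encodes a secreted Wnt regulator. Of the basal and myoepithelial list 10 of 20 fell, none rose and 10 did not pass (0 and 14 adjusted over the list alone). A median of -1.25 was found over the list (camera adjusted p = 1.1e-11, adjusted p = 0.16 with an estimated correlation). Further luminal genes that rose were Krt8 (1.17), Krt18 (1.46), Epcam (1.08), Esr1 (1.27), Pgr (1.60) and Elf5 (2.57), and Trp63 (-1.29) fell. The largest falls included Frmpd4 (-4.14), Brinp3 (-3.94) and Lrrtm1 (-3.61), genes best known from neurons. Immediate-early stress genes also fell, with Egr2 (-1.99). Of that list 5 of 21 fell, none rose and 16 did not pass (0 and 13 adjusted over the list alone). Members had a median of -0.98 (camera adjusted p = 3.2e-09, adjusted p = 0.15 with an estimated correlation). Of TGF-beta and BMP targets, with Ccn2 (-1.82), a matrix protein gene, 1 of 16 rose, 4 fell and 11 did not pass (1 and 6 adjusted over the list alone). Over all its genes the median was -0.60 (camera adjusted p = 0.0020, adjusted p = 0.43 with an estimated correlation). Of the Wnt list, with Lgr5 (-2.31) and Wif1 (-2.26) lower and Ccnd1 (3.52) higher, 1 of 14 rose, 4 fell and 9 did not pass (1 and 5 adjusted over the list alone). The list median was -0.78 log2 units (camera adjusted p = 0.14, adjusted p = 0.63 with an estimated correlation). The Notch list ran both ways, with Notch3 (2.03) and Dtx4 (1.56) higher and Dll1 (-1.50) lower, and 2 of 18 rose, 2 fell and 14 did not pass (2 and 2 adjusted over the list alone). Its members had a median log2 fold change of 0.59 (camera adjusted p = 0.44, adjusted p = 0.82 with an estimated correlation). Further, 2 of 17 p53 targets rose, among them Zmat3 (1.51), and 2 of 15 epithelial-mesenchymal transition regulators, among them Fn1 (3.81). Notch3 is also a pericyte gene, and pericyte (median 1.27, camera adjusted p = 0.037, and adjusted p = 0.49 with an estimated correlation) and fibroblast genes (median 2.04, camera adjusted p = 0.0050, and adjusted p = 0.43 with an estimated correlation) had positive medians here. Among progenitor and alveolar genes 6 of 16 rose, 1 fell and 9 did not pass (6 and 1 adjusted over the list alone). Their median log2 fold change was 1.14 (camera adjusted p = 0.00054, adjusted p = 0.43 with an estimated correlation). Among interferon-stimulated genes 3 of 24 rose, none fell and 21 did not pass (10 and 0 adjusted over the list alone). The median over these genes was 1.52 (camera adjusted p = 6.0e-07, adjusted p = 0.43 with an estimated correlation). Their mean was 4.96 log2 CPM in THC replicate 1 but 3.74 in THC replicate 2, against 2.92 and 2.70 in BC replicates 1 and 2. The quasi-likelihood test of edgeR called 987 genes higher and 537 lower in THC, and camera 15 of 25 lists, of which the pan-luminal and hormone-sensing lists held with an estimated correlation. The total was 935 without BC replicate 1, 280 without BC replicate 2, 545 without THC replicate 1 and 475 without THC replicate 2. Without BC replicate 1, adjusted p lay between 0.056 and 0.093 for Dtx4, Epcam, Esr1, Krt18, Krt8, Pgr and Trp63. Without BC replicate 2, adjusted p lay between 0.062 and 0.25 for Dll1, Dtx4, Elf5, Epcam, Krt18, Krt8, Lgr5, Trp63 and Wif1. Without THC replicate 1, adjusted p lay between 0.061 and 0.30 for Dll1, Epcam, Krt18, Krt8, Lgr5, Trp63 and Wif1. Without THC replicate 2, adjusted p lay between 0.059 and 0.098 for Dll1, Dtx4, Elf5, Epcam, Esr1, Krt18, Krt8, Lgr5, Pgr and Wif1.

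**Figure D2:**
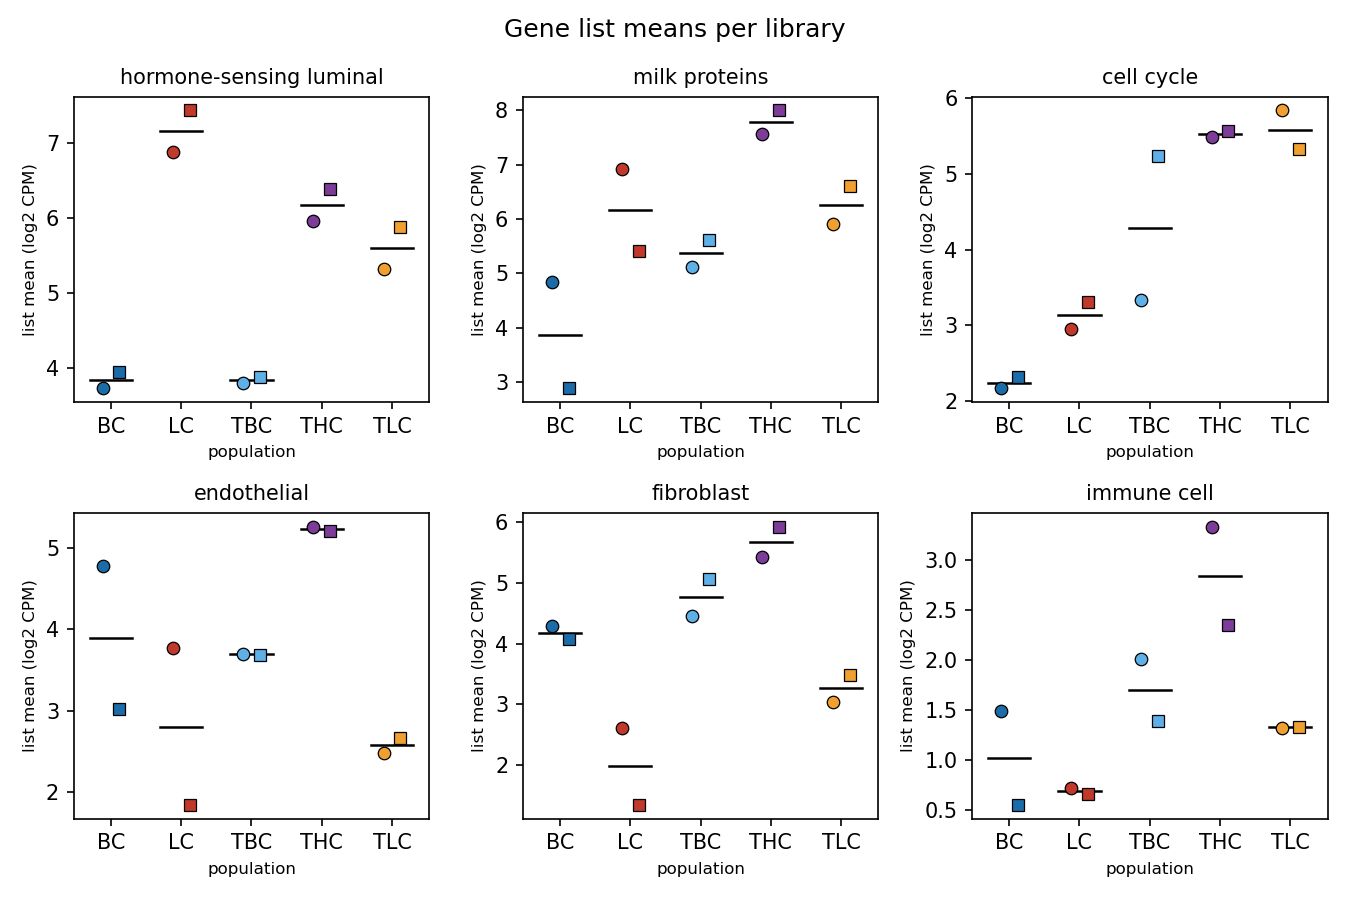
Mean log2 CPM of 6 gene lists, 1 panel per list, for each library of BC, LC, TBC, THC and TLC. The endothelial mean is 5.24 ± 0.04 (SD, n = 2) in THC and 2.57 ± 0.13 (SD, n = 2) in TLC, and the milk protein mean is highest in THC.

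THC and TBC both followed ablation and both carried Tomato, so they were compared to learn what marks the hybrid population where neither factor differs. Luminal genes rose, with Krt19, a simple-epithelium keratin, at 485 ± 83.6 CPM in THC against 85.1 ± 23.4 in TBC (SD, n = 2 each) and Cldn7 at 56.7 ± 3.64 CPM in THC against 8.75 ± 0.351 in TBC (SD, n = 2 each). Areg, an EGFR ligand downstream of estrogen, rose to 206 ± 26.4 CPM in THC against 25.5 ± 8.21 in TBC (SD, n = 2 each). Tagln, a contractile gene of myoepithelium, fell to 378 ± 42.3 CPM in THC against 1266 ± 312 in TBC (SD, n = 2 each). Krt14 stood at 895 ± 378 CPM in THC against 1527 ± 278 in TBC (SD, n = 2 each). The differences of Krt5 (-1.03, adjusted p = 0.28), Krt14 (-0.77, adjusted p = 0.49) and Acta2 (-1.48, adjusted p = 0.10) did not pass. Pan-luminal genes that rose included Cldn7 (2.69), Cldn3 (2.19), Krt19 (2.51) and Krt18 (2.16). Of that list 14 of 20 rose, none fell and 6 did not pass (17 and 0 adjusted over the list alone). Across that list the median was 2.17 (camera adjusted p = 2.8e-33, adjusted p = 0.0029 with an estimated correlation). Hormone-sensing genes that rose included Areg (3.03), Foxa1 (3.16) and Cited1 (3.26). Of that list 9 of 14 rose, none fell and 5 did not pass (12 and 0 adjusted over the list alone). A median of 2.57 was found over the list (camera adjusted p = 1.6e-27, adjusted p = 0.021 with an estimated correlation). Of progenitor and alveolar genes, with Wfdc18 (2.60) and Elf5 (2.88), where Elf5 drives alveolar fate, 8 of 16 rose, none fell and 8 did not pass (11 and 0 adjusted over the list alone). Members had a median of 2.31 (camera adjusted p = 3.1e-12, adjusted p = 0.26 with an estimated correlation). Of basal and myoepithelial genes, with Tagln (-1.74) and Dkk3 (-1.57), 9 of 20 fell, none rose and 11 did not pass (0 and 16 adjusted over the list alone). Over all its genes the median was -1.53 (camera adjusted p = 6.1e-22, adjusted p = 0.062 with an estimated correlation). Without TBC replicate 1, adjusted p lay between 0.058 and 0.082 for Dkk3, Elf5 and Tagln. Without TBC replicate 2, adjusted p was 0.12 for Krt18. Without THC replicate 1, adjusted p lay between 0.056 and 0.067 for Dkk3 and Krt18. Without THC replicate 2, adjusted p lay between 0.066 and 0.073 for Dkk3 and Tagln.

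Outside these lists the largest rises in THC against TBC included Cyp24a1 (3.66), Cxcl15 (3.34) and Myo5c (3.28), a vitamin D-degrading enzyme, a chemokine of epithelia and a secretory myosin. The largest falls included Xkr4 (-2.59), Lrrtm1 (-2.54) and Brinp3 (-2.21). Anchor genes that rose were Krt8 (1.46), Epcam (1.54), Esr1 (1.59), Pgr (1.44) and Tnf (2.23), and Trp63 (-1.58) fell. Ccnd1 (1.90) rose among Wnt targets, of which 1 of 14 rose, 3 fell and 10 did not pass (1 and 9 adjusted over the list alone). The list median was -0.88 log2 units (camera adjusted p = 0.00015, adjusted p = 0.38 with an estimated correlation). Of TNF and NF-kappaB targets, with Tnf, 3 of 23 rose, none fell and 20 did not pass (4 and 0 adjusted over the list alone). Its members had a median log2 fold change of 0.51 (camera adjusted p = 0.0021, adjusted p = 0.43 with an estimated correlation). Cell cycle genes had a median of 1.14 with 0 called (adjusted p = 0.43 with an estimated correlation), and milk protein genes 2.75 with 2 called (adjusted p = 0.28 with an estimated correlation). By edgeR's quasi-likelihood test 508 genes were higher and 226 lower, against 1385 in all by DESeq2, 1243 with only THC and TBC in the fit and 337 with the endothelial list mean as a covariate. The total was 177 without TBC replicate 1, 222 without TBC replicate 2, 322 without THC replicate 1 and 208 without THC replicate 2. Without TBC replicate 1, adjusted p lay between 0.058 and 0.20 for Brinp3, Epcam, Esr1, Krt8, Lrrtm1, Pgr, Trp63 and Xkr4. Without TBC replicate 2, adjusted p lay between 0.056 and 0.27 for Epcam, Esr1, Krt8, Lrrtm1, Pgr, Tnf and Trp63. Without THC replicate 1, adjusted p lay between 0.055 and 0.25 for Epcam, Krt8, Lrrtm1, Pgr, Tnf, Trp63 and Xkr4. Without THC replicate 2, adjusted p lay between 0.060 and 0.18 for Brinp3, Esr1, Krt8, Lrrtm1, Pgr, Tnf and Xkr4.

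THC was set against TLC and LC to learn how hybrid cells depart from luminal cells. Basal genes were higher in THC than in TLC, with Acta2 at 1144 ± 209 CPM in THC against 56.8 ± 1.67 in TLC (SD, n = 2 each), and pan-luminal genes were lower in part. Against TLC, of the basal and myoepithelial list 13 of 20 rose, none fell and 7 did not pass (16 and 0 adjusted over the list alone). Their median log2 fold change was 2.11 (camera adjusted p = 2.1e-48, adjusted p = 0.029 with an estimated correlation). Against LC, 17 of 20 rose, none fell and 3 did not pass (20 and 0 adjusted over the list alone). The median over these genes was 4.89 (camera adjusted p = 1.8e-60, adjusted p = 0.013 with an estimated correlation). Of the pan-luminal list against TLC, 2 of 20 fell, none rose and 18 did not pass (0 and 7 adjusted over the list alone). Across that list the median was -0.53 (camera adjusted p = 7.2e-09, adjusted p = 0.040 with an estimated correlation). Of the same list against LC, 14 of 20 fell, none rose and 6 did not pass (0 and 16 adjusted over the list alone). A median of -1.32 was found over the list (camera adjusted p = 1.4e-13, adjusted p = 0.015 with an estimated correlation). Against TLC, edgeR's quasi-likelihood test called 300 genes higher and 18 lower in THC, and against LC 1760 and 791. DESeq2 called 782 genes against TLC, limma-voom 332 and edgeR without the low-count filter 1143. Against TLC the total was 83 with the endothelial list mean as a covariate, 171 without THC replicate 1, 57 without THC replicate 2, 60 without TLC replicate 1 and 0 without TLC replicate 2. Without TLC replicate 1, adjusted p was 0.058 for Acta2. Without TLC replicate 2, adjusted p was 0.11 for Acta2. Against LC the total was 1088 with that covariate, 1191 without LC replicate 2, 1332 without THC replicate 1 and 1266 without THC replicate 2.

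Mean levels of endothelial, fibroblast, pericyte and immune marker lists were highest in both THC libraries. Pecam1, an adhesion protein of blood vessels, stood at 172 ± 15.98 CPM in THC against 32.6 ± 1.81 in TLC (SD, n = 2 each) and 51.4 ± 3.07 (SD, n = 2) in TBC. Col1a1, a fibroblast collagen, stood at 482 ± 336 CPM in THC against 81.2 ± 71.97 in TLC (SD, n = 2 each) and 104 ± 36.3 (SD, n = 2) in TBC. Against TLC these single genes did not pass (Pecam1, 2.40, adjusted p = 0.21 and Col1a1, 2.56, adjusted p = 0.18). Of endothelial genes against TLC, 3 of 16 rose, none fell and 13 did not pass (16 and 0 adjusted over the list alone). Members had a median of 2.80 (camera adjusted p = 1.5e-19, adjusted p = 0.22 with an estimated correlation). Of fibroblast genes 1 of 15 rose, none fell and 14 did not pass (14 and 0 adjusted over the list alone). Over all its genes the median was 2.56 (camera adjusted p = 6.1e-15, adjusted p = 0.12 with an estimated correlation). Of pericyte genes 3 of 9 rose, none fell and 6 did not pass (5 and 1 adjusted over the list alone). The list median was 2.63 log2 units (camera adjusted p = 2.9e-06, adjusted p = 0.22 with an estimated correlation). Of immune genes 1 of 18 rose, none fell and 17 did not pass (6 and 0 adjusted over the list alone). Its members had a median log2 fold change of 1.70 (camera adjusted p = 9.0e-08, adjusted p = 0.22 with an estimated correlation). Against BC the medians were 1.19 for endothelial genes (adjusted p = 0.50 with an estimated correlation), 2.04 for fibroblast genes (adjusted p = 0.43 with an estimated correlation) and 2.001 for immune genes (adjusted p = 0.33 with an estimated correlation). Against TBC the endothelial median was 1.67 (adjusted p = 0.43 with an estimated correlation). The other medians against TBC were 1.74 for fibroblast, 1.43 for pericyte and 1.22 for immune genes. Both THC libraries exceeded all 4 TBC and TLC libraries for 16 of 16 endothelial, 11 of 18 immune, 9 of 15 fibroblast and 6 of 9 pericyte genes, against 6.67% of genes by chance. The same held for 7 of 9 milk protein genes, including Csn2, Lalba and Xdh, and for 6 of 14 hormone-sensing genes, including Areg, Pgr and Wnt4. It also held for 8 of 15 epithelial-mesenchymal transition regulators, including Fn1, Twist1 and Zeb1, but for 0 basal and 0 pan-luminal genes. Members of a list can move together, so 6.67% applies to single genes and gives no test of a list. Of the 11592 genes with at least 10 CPM in TBC, THC or TLC, 596 lay above and 568 below, which is 5.14% and 4.90%. List members were not limited by level, and of all 19757 tested genes 1456 lay above and 824 below, or 7.37% and 4.17%. Rgs1 (ENSMUSG00000026358, 1:144242296-144249242), a brake on G-protein signals in lymphocytes and other cells, passed against all 4 other populations, at 14.7 ± 2.76 (SD, n = 2) CPM in THC against 2.68 to 3.96 elsewhere. Sfrp4, a secreted Wnt regulator chosen after its values were seen, was the only other gene to do so, at 3.26 ± 0.318 (SD, n = 2) CPM, and 0 genes passed below all 4. Genes apart in this way numbered 8 without BC replicate 1, 18 without LC replicate 1, 4 without LC replicate 2 and 1 without TBC replicate 1, and 0 without BC replicate 2, TBC replicate 2 or either TLC library.

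TLC and LC were compared to learn how Tomato luminal cells after ablation differ from control luminal cells. Basal keratins rose, with Krt14 at 528 ± 209 CPM in TLC against 22.7 ± 17.1 in LC (SD, n = 2 each) and Krt5 at 129.5 ± 68.4 CPM in TLC against 8.62 ± 4.06 in LC (SD, n = 2 each). The smooth muscle actin Acta2 (1.27, adjusted p = 0.12) did not pass. Dsc3 (ENSMUSG00000059898, 18:19960930-20002351), a desmosome gene of stratified epithelium, rose as well, at 28.3 ± 8.11 CPM in TLC against 0.234 ± 0.128 in LC (SD, n = 2 each). Hormone-sensing genes fell, with Esr1 at 101 ± 15.5 CPM in TLC against 456 ± 78.8 in LC (SD, n = 2 each) and Areg at 96.5 ± 18.3 CPM in TLC against 416 ± 53.1 in LC (SD, n = 2 each). Cell division genes rose, with Mki67 at 524 ± 82.4 CPM in TLC against 40.9 ± 17.8 in LC (SD, n = 2 each). Basal genes that rose included Krt14 (4.55), Krt5 (3.92), Trp63 (2.72), Cdh3 (4.48), Tpm2 (2.87) and Jag2 (1.86). Of that list 12 of 20 rose, none fell and 8 did not pass (14 and 0 adjusted over the list alone). Their median log2 fold change was 1.94 (camera adjusted p = 1.1e-22, adjusted p = 0.11 with an estimated correlation). Krt14 in TLC replicates 1 and 2 amounted to 44.3% and 24.9% of its TBC mean and Krt5 to 16.4% and 7.49%. Contractile genes of the fixed list lay lower, with Tpm2 at 9.74% and 7.05%, Mylk at 5.92% and 4.49% and Acta2 at 1.74% and 1.82%. Myh11, a myosin of smooth muscle, stood at 1.03% and 1.56% and Cnn1 at 0.670% and 1.24%. Cald1, which is not on that list and was named after its values were seen, stood at 42.5% and 25.3%. Among hormone-sensing genes, with Esr1 (-2.17), Pgr (-2.15), Areg (-2.11) and Wnt4 (-2.32), 6 of 14 fell, none rose and 8 did not pass (0 and 9 adjusted over the list alone). The median over these genes was -2.12 (camera adjusted p = 2.2e-12, adjusted p = 0.11 with an estimated correlation). Among pan-luminal genes, with Elf3 (-1.18), an epithelial differentiation factor, 4 of 20 fell, none rose and 16 did not pass (1 and 6 adjusted over the list alone). Across that list the median was -0.69 (camera adjusted p = 6.7e-05, adjusted p = 0.11 with an estimated correlation). The luminal keratins and Epcam did not pass, with Krt8 (-0.65, adjusted p = 0.26), Krt18 (-0.97, adjusted p = 0.14), Krt19 (-0.82, adjusted p = 0.081) and Epcam (-0.58, adjusted p = 0.24), nor did Elf5 (-0.23, adjusted p = 0.82) and Tnf (-1.06, adjusted p = 0.13). Without LC replicate 1, adjusted p was 0.016 for Acta2. Without LC replicate 2, adjusted p was 0.042 for Tnf. Without TLC replicate 1, adjusted p was 0.057 for Mki67.

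Cell cycle genes rose in TLC against LC, with Mki67 (3.68). Of that list 22 of 28 rose, none fell and 6 did not pass (24 and 0 adjusted over the list alone). A median of 2.998 was found over the list (camera adjusted p = 5.7e-21, adjusted p = 0.28 with an estimated correlation). Squamous genes that rose included Dsc3 (6.93), Dsg3 (6.66) and Lgals7 (3.20). Of that list 5 of 17 rose, none fell and 12 did not pass (7 and 1 adjusted over the list alone). Members had a median of 0.73 (camera adjusted p = 2.0e-05, adjusted p = 0.28 with an estimated correlation). Wnt targets that rose included Nkd2 (4.52), Ccnd1 (1.37) and Lgr5 (4.03), a stem cell marker of several epithelia that stood at 320 CPM in TBC. Of that list 6 of 14 rose, none fell and 8 did not pass (8 and 0 adjusted over the list alone). Over all its genes the median was 0.87 (camera adjusted p = 1.3e-07, adjusted p = 0.24 with an estimated correlation). Of TNF and NF-kappaB targets 5 of 23 fell, none rose and 18 did not pass (1 and 11 adjusted over the list alone). The list median was -0.63 log2 units (camera adjusted p = 0.0013, adjusted p = 0.51 with an estimated correlation). Embryonic mammary genes had Bcl11b (5.58), a transcription factor of stem cells, among the rises and Fgfr2 (-1.95), a growth factor receptor, as the fall (4 of 17 rose, 1 fell and 12 did not pass, 6 and 3 adjusted over the list alone, median 0.96, camera adjusted p = 0.040, and adjusted p = 0.41 with an estimated correlation). The rise of Sez6, a gene of neuronal dendrites with few counts in LC, was 156-fold with a counting interval of 52.9 to 759.5 (95% confidence). Further rises were of Fn1 (3.18) and Phlda3 (1.81), which encode fibronectin of the matrix and a p53 target. Fn1 is 1 of the epithelial-mesenchymal transition regulators, which were higher in TLC as a list (median 1.96, camera adjusted p = 0.00027, and adjusted p = 0.41 with an estimated correlation), as were fibroblast genes (median 1.09, camera adjusted p = 0.0051, and adjusted p = 0.46 with an estimated correlation). For immune genes the list did not pass (median 0.99, camera adjusted p = 0.066, and adjusted p = 0.72 with an estimated correlation). Muc16 (-4.59), Trpc6 (-4.01), Mgat3 (-3.90) and Herpud1 (-2.15) fell, which encode a mucin, a cation channel, a glycan-building enzyme and a stress protein of the endoplasmic reticulum. In total, edgeR's quasi-likelihood test called 881 genes higher and 744 lower, and camera 13 of 25 lists, none of which held with an estimated correlation. The total was 719 without LC replicate 2 and 494 without TLC replicate 1. Without TLC replicate 1, adjusted p was 0.057 for Mki67.

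**Figure D3:**
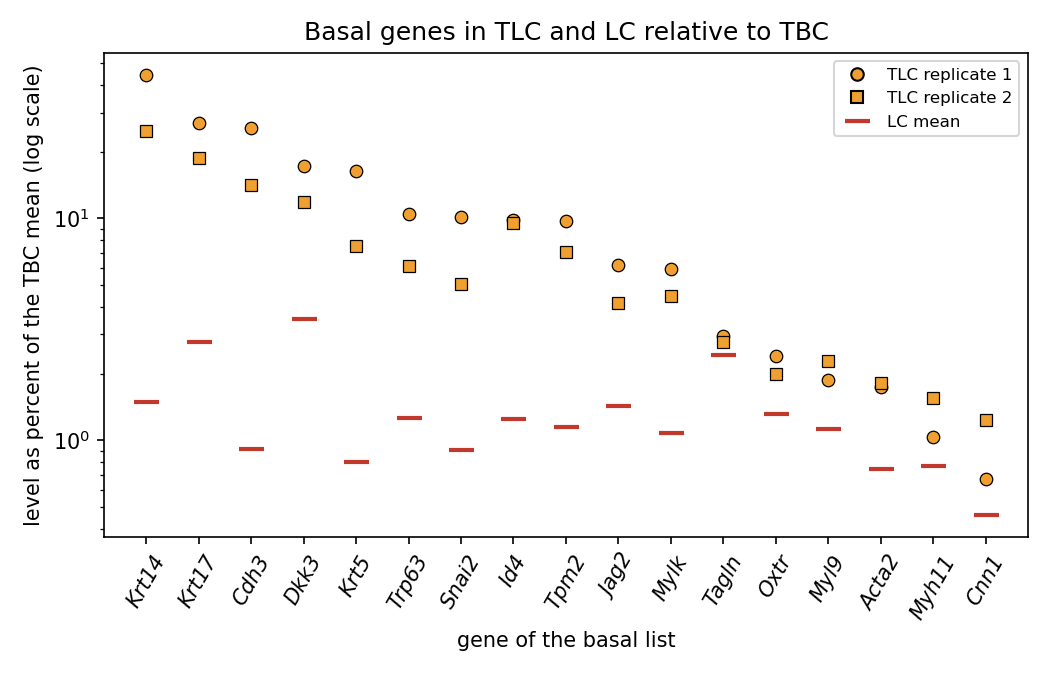
Level in each TLC library of 17 genes of the basal and myoepithelial list as a percentage of the TBC mean, on a log axis with 1 point per library. Krt14 reaches 44.3% and 24.9% while Cnn1 lies at 0.670% and 1.24%.

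TLC and TBC were compared to learn whether both lineages stayed distinct after ablation. They differed along the lineage lists, with Krt8 at 1322 ± 135 CPM in TLC against 301 ± 84.7 in TBC (SD, n = 2 each) and Acta2 at 56.8 ± 1.67 CPM in TLC against 3192 ± 637 in TBC (SD, n = 2 each). Of basal and myoepithelial genes 18 of 20 were lower, none were higher and 2 did not pass (0 and 19 adjusted over the list alone). Its members had a median log2 fold change of -3.59 (camera adjusted p = 1.6e-46, adjusted p = 0.018 with an estimated correlation). Of pan-luminal genes 18 of 20 were higher, none were lower and 2 did not pass (18 and 0 adjusted over the list alone). Their median log2 fold change was 2.32 (camera adjusted p = 6.7e-33, adjusted p = 0.0029 with an estimated correlation). By the same quasi-likelihood test 1105 genes were higher and 1584 lower in TLC. The total was 1643 without TBC replicate 1, 1577 without TBC replicate 2 and 1484 without TLC replicate 2.

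The difference of differences, TLC minus LC against TBC minus BC, asked whether luminal and basal cells departed unequally from their controls. Basal genes rose more on the luminal side, with Krt14 differing by 5.13 ± 0.76 (SE) log2 units (adjusted p = 0.016). Krt5 differed by 3.92 ± 0.67 (SE) (adjusted p = 0.029) and Dsc3 by 6.08 ± 0.66 (SE) (adjusted p = 0.0040). Tox, a nuclear factor known from T cells, differed by 5.27 ± 0.78 (SE) (adjusted p = 0.011) and Mgat3 by -4.48 ± 0.69 (SE) (adjusted p = 0.015). Of the basal and myoepithelial list 7 of 20 rose, none fell and 13 did not pass (11 and 0 adjusted over the list alone). The median over these genes was 1.72 (camera adjusted p = 1.4e-20, adjusted p = 0.088 with an estimated correlation). Of the hormone-sensing list 5 of 14 fell, none rose and 9 did not pass (0 and 6 adjusted over the list alone). Across that list the median was -2.07 (camera adjusted p = 3.5e-14, adjusted p = 0.088 with an estimated correlation). In all 109 genes were higher and 71 lower in this difference. The total was 113 without BC replicate 1, 98 without BC replicate 2, 100 without LC replicate 2, 69 without TBC replicate 1, 45 without TBC replicate 2, 65 without TLC replicate 1 and 116 without TLC replicate 2. Without BC replicate 1, adjusted p was 0.05003 for Krt14. Without BC replicate 2, adjusted p lay between 0.052 and 0.073 for Krt14 and Krt5. Without LC replicate 2, adjusted p was 0.064 for Krt5. Without TBC replicate 1, adjusted p lay between 0.074 and 0.11 for Krt14 and Krt5. Without TBC replicate 2, adjusted p lay between 0.058 and 0.12 for Krt14, Krt5, Mgat3 and Tox. Without TLC replicate 1, adjusted p lay between 0.078 and 0.086 for Krt14, Krt5 and Mgat3.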

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

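Of the tests used here, the mixture of shares and the second endothelial list were fixed before their values were seen, while the counts of genes with a share above 1, the depth of THC replicate 1 in both of its tests, the range of TLC to TBC ratios and the gap between library sets were chosen only after the results were seen.

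The departure from controls differed between luminal and basal cells for 109 genes higher and 71 genes lower in TLC minus LC than in TBC minus BC. The largest differences of differences upward, in log2 units, were those of Sez6 (8.46), Frmpd4 (7.55), Dsc3 (6.08), Colca2 (5.63), Tox (5.27) and Col10a1 (5.15). Sez6 and Frmpd4 had 3 counts or fewer in LC, so the size of their values depends on the prior count. The largest downward were Mgat3 (-4.48), Pcdha9 (-3.97), Pcdha1 (-3.94), Pcdha4 (-3.93), Pcdha6 (-3.92) and Pcdha5 (-3.92). The protocadherin alpha genes share their constant exons, so the 5 values are best read as 1 signal of that locus, which stood near 69.5 CPM in LC and 5.18 in TLC for Pcdha1. Leaving out 1 library in turn, of 8 such fits, the call was lost in 5 for Sez6, 7 for Frmpd4, 0 for Dsc3, 4 for Colca2, 1 for Tox, 4 for Col10a1 and 2 for Mgat3, and in 6 for each protocadherin alpha gene.

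Shares of reads that were not assigned to genes also exceeded the range of the control libraries in some Tomato libraries. TLC replicate 2 had 30.8% of reads without a feature, where controls reached 27.4%. Ambiguous reads made up 3.18% in TBC replicate 1, 3.48% in TLC replicate 1 and 3.19% in TBC replicate 2, where controls reached 3.11%. THC replicate 1 had 43.0% of reads without a unique alignment, against 15.6% to 22.4% in controls.

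Levels of THC between TBC and TLC may come from a mixture of both cell types in the THC sort, from cells that each express both programs, or from the low depth of THC replicate 1. A mixture predicts the same luminal share from luminal and from basal genes. In THC replicate 1 the median share was 0.608 from 385 luminal genes and 0.726 from 690 basal genes, a difference of -0.118, and in THC replicate 2 it was 0.737 and 0.678, a difference of 0.0589, both within the bound of 0.15 set beforehand. In THC replicates 1 and 2, 23.1% and 30.6% of the luminal genes had a share above 1, which is a level above TLC. For basal genes a share above 1 is a level below TLC, found for 6.96% and 1.74%. A share below 0, for basal genes a level above TBC, was found for 5.36% and 1.74% of basal and 0% of luminal genes. The share that spread between libraries would give was not computed. Cells expressing both programs were not tested, so both explanations stay open. Depth is ruled out as the cause, since the deep THC replicate 2 had a median share of 0.686 against 0.702 in THC replicate 1.

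Basal genes in TLC may come from TBC cells that entered the TLC sort, from a difference between the sets of libraries, or from basal genes being expressed in Tomato luminal cells. A single share of TBC cells predicts 1 ratio of TLC to TBC for all basal genes. Yet over 152 genes the upper decile of that ratio exceeded the lower by 8.93-fold in TLC replicate 2 and 18.9-fold in TLC replicate 1. All 152 stayed within 2-fold of their mean in TBC, but as that mean came from the same libraries, this is a loose measure of spread. The ratios were not corrected for counting error or for the LC level. Their log2 values correlated at 0.833 between the TLC libraries. The first bound, under 50% of genes within 2-fold of the median ratio, was met in TLC replicate 1 (41.4%) but not in TLC replicate 2 (63.2%). A TBC share near the lower decile, 0.0195 and 0.0226, and other basal-type cells remain open. The sets do not account for it, as the lower TLC basal mean exceeded the higher LC mean by 1.56 log2 units where the LC libraries differed by 0.668.

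Endothelial, fibroblast, pericyte and immune markers in THC may come from such cells in the sort, from these genes being expressed in hybrid cells, or from the low depth and many multi-mapped reads of THC replicate 1. Cells of these types predict that other genes of the same type follow. Of a second endothelial list, 19 of 20 genes (95%) were higher in both THC libraries than in all TBC and TLC libraries. The rate by chance is 6.67% for a single gene, but members of a list can move together. BC and LC were not part of this count. The first endothelial list averaged 4.78 log2 CPM in BC replicate 1, against 5.26 and 5.21 in THC replicates 1 and 2. Expression in hybrid cells was not tested and bulk counts cannot exclude it. Depth is excluded for the endothelial list, where THC replicate 2 exceeded every TBC and TLC library by 1.51 log2 units while the THC libraries differed by 0.0508, and the fibroblast (0.85 against 0.49) and pericyte (0.67 against 0.46) lists met the same rule, but for the immune list (0.34 against 0.98) depth stays open.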

How the results depend on the processing

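With 2 libraries per population and ablation tied to Tomato marking, the counts called depend on the filter, the tool and on keeping all libraries. A fit without 1 library also loses degrees of freedom, so a changed count cannot be laid to that library. Of the 311 gene results followed over 4390 alternatives, none changed direction where the gene was called in either fit. Genes called in neither fit were not checked for direction, and gene calls were lost in part of the alternatives. No list call changed direction over 675 alternatives, with estimated correlation, fry and the block. Of these, 197 lost the call and 10 gained one. Lineage list means moved by no more than their SD with RLE factors and with a prior count of 0.5. Leaving out either library was no test of them, because with 2 libraries a mean then always moves by less than its SD.

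Leaving out each library in turn gave 3131 to 3685 for LC vs BC (4742 with all), 0 to 148 for TBC vs BC (0 with all), 280 to 935 for THC vs BC (1524 with all), 177 to 322 for THC vs TBC (734 with all), 494 to 1107 for TLC vs LC (1625 with all), 1191 to 1741 for THC vs LC (2551 with all), 0 to 171 for THC vs TLC (318 with all), 1484 to 1889 for TLC vs TBC (2689 with all), 45 to 268 for the difference of differences (180 with all) and 0 to 18 for genes apart in THC (2 with all).

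Without the low-count filter the counts were 398 for TBC vs BC, 2707 for THC vs BC, 1839 for THC vs TBC, 2561 for TLC vs LC, 1143 for THC vs TLC, 725 for the difference of differences and 69 for genes apart in THC. With DESeq2 they were 207 for TBC vs BC, 1385 for THC vs TBC, 782 for THC vs TLC, 505 for the difference of differences and 27 for genes apart in THC, and with limma-voom 105 for the difference of differences and 19 for genes apart in THC. With the endothelial list mean as a covariate they were 6 for TBC vs BC, 337 for THC vs TBC, 1088 for THC vs LC, 83 for THC vs TLC, 300 for the difference of differences and 8 for genes apart in THC. The endothelial covariate was itself highest in both THC libraries, so it overlaps with the THC population, and fewer calls cannot be laid to endothelial cells. With only both populations in the fit the count was 1243 for THC vs TBC, and with thinned counts 1 for genes apart in THC. Of 225 list tests, camera with preset correlation called 127, camera with an estimated correlation 13 and fry 53.

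The replicate block, the set of library numbers as a term, gave 33 for TBC vs BC, 2800 for THC vs BC, 1510 for THC vs TBC, 2527 for TLC vs LC, 683 for THC vs TLC, 425 for the difference of differences and 45 for genes apart in THC. Deviations from the group means correlated above 0.1 in 8 of 10 pairs of populations, from -0.0124 to 0.421, so the sets share some variation, and the cause was not tested. Upper-quartile factors left the count of the difference of differences near its value but moved its split to 136 higher and 41 lower.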

Other observations

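In THC, 12 genes were called above both TBC and TLC, and 0 below both. In all 12 both THC libraries lay above every TBC and TLC library, which calling them above both favours. Their log2 fold changes ran from 1.24 to 3.66 against TBC and from 1.22 to 4.65 against TLC. Without a TBC, THC or TLC library most of these calls were lost. Such a fit leaves a population with a single library, so a lost call cannot be laid to the library left out. With the endothelial list mean as a covariate 2 held. That mean was itself highest in THC, at 5.26 and 5.21 log2 CPM in replicates 1 and 2. The covariate thus takes up differences of THC from other populations, so lost calls cannot be laid to endothelial cells. LC stood highest for 5 of the 12 genes. Tmem56, a lipid-related membrane protein gene, stood at 1603 CPM in LC, 434 in THC and 164 in TLC, the mechanosensitive channel gene Piezo2 at 339, 73.5 and 27.0, and Trpc6 at 113, 20.8 and 6.83. Galnt15 and H2-Q6 followed the same order. The other 7, Ace, Lipa, Rgs1, Egfl7, Cyp24a1, Sfrp4 and Gimap8, had their highest mean in THC, where endothelial, fibroblast, pericyte and immune markers were highest too, and Egfl7 is a gene of the endothelial list. Of hormone-sensing and milk protein genes, both THC libraries lay above all TBC and TLC libraries for 6 of 14 and 7 of 9 genes. The rate by chance is 6.67% for a single gene, but members of a list can move together. The hormone-sensing mean was 7.16 log2 CPM in LC and 6.17 in THC, and the milk protein mean 6.16 in LC and 7.78 in THC.

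Genes called in TLC against LC mostly moved in the same direction in TBC against BC, where no gene passed. Of 1625 genes called in TLC against LC, 1216 had the same sign in TBC against BC (74.8%), and 26 of 28 cell cycle genes did. The same-sign share over all genes was not computed. The correlation of both log2 fold changes was 0.390 across 19757 genes and 0.383 without the cell cycle list. Both contrasts use separate libraries, but these are not fully independent. Differences between replicates correlated at 0.408 between BC and LC and at 0.0854 between TBC and TLC. Variation shared by the controls may therefore add to the correlation. Both contrasts also share Tomato marking, and the mouse lines are not given.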
